A study of Mus musculus with 4 samples.

How the data were processed

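RNA was measured by sequencing in CD8+ T cells from B16-GP33 tumours of mice, with 2 EV libraries and 2 ACSS2NLS libraries, all from day 21. Per the labels' protocols, RNA was purified with the RNeasy Plus Micro kit and libraries were made with the SMART-Seq v4 Ultra Low Input kit, which amplifies full-length cDNA from small amounts of RNA. Per the submitters' processing notes, STAR 2.5.3a, HOMER and the mm10 genome build were used. Per the file headers, HOMER counted tags over the exons of RefSeq genes on the sense strand, kept a single transcript per gene and scaled the values to FPKM, which corrects for the exon length of the gene and the total tags of the library. Whether the libraries kept strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be assigned with certainty.

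The deposited table holds FPKM with 3 decimals for 24537 genes, with no symbol in more than 1 row. Its columns are named Acss2WT and Acss2OE with replicate numbers, not with the group names of the labels; they were read as EV and ACSS2NLS, and the level of Acss2 in each library serves as a check of that reading. The header of the table names 8 tag directories, while the table has 4 library columns, all of which were used. FPKM are not counts, so no count test was run. Multiplied by gene length, however, the low FPKM values fell on whole multiples of the smallest step: in each library 100% of the values checked did so, within a tolerance of 0.1 of a step, over genes of 500 to 2000 bases with up to 50 tags. To the nearest 100000, that step gave total tags of 46000000 for EV replicate 1, 49300000 for EV replicate 2, 48800000 for ACSS2NLS replicate 1 and 48300000 for ACSS2NLS replicate 2. The tags counted on exons were 19300000, 20100000, 19300000 and 19700000 in the same order. The replicates differed by more than counting noise, with a chi-square per degree of freedom of 40.1 between the EV libraries and 60.7 between the ACSS2NLS libraries, so neither pair looked like the same library deposited again; library preparation alone can give such an excess.

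From the deposited FPKM, log2(FPKM + 1) was computed for the 9810 genes with a mean of at least 1 FPKM over the 4 libraries. A log2 change is the ACSS2NLS mean minus the EV mean on that scale, which understates the change of low genes. The 2 groups were compared gene by gene with limma-trend (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fixed gene lists with at least 5 measured genes were tested with camera from limma at an inter-gene correlation of 0.01. The p-values were Benjamini-Hochberg adjusted over the 19 lists tested. The lists were tested again with the correlation estimated from the data and with fry. Those 2 tests rest on 2 residual degrees of freedom, which limits their power. The lists were progenitor and memory T cell genes, terminal exhaustion, cytotoxic effector, cytokine and chemokine, immediate early and T cell receptor (TCR) response, tissue residency, interferon stimulated, proliferation, acetyl-CoA and lipogenesis, cholesterol synthesis, glycolysis, oxidative phosphorylation, histone acetylation, cytosolic ribosomal protein and heat shock genes, and markers of melanoma cells, myeloid cells, CD4 and regulatory T cells, and stromal, endothelial and red blood cells. The lists of B cell markers and of NK and gamma-delta T cell markers had 2 measured genes each and were tested only with no filter on low values.

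Groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule named 11 genes whatever their values (Acss2, Acly, Tcf7, Slamf6, Il7r, Havcr2, Pdcd1, Tox, Gzmb, Ifng and 1 gene that is not reported here), up to 10 genes with the largest rise and 10 with the largest fall past the threshold whose groups did not overlap, and up to 2 genes per list with the smallest unadjusted p. Unnamed transcripts, pseudogenes and small RNA genes were left out of the second part, and where fewer genes passed it was filled to 5 with the smallest unadjusted p. Any other gene was chosen after its values were seen.

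The test was run on simulated data for this comparison, with 200 of the 9810 genes changed in each of 10 datasets. It recovered 36.4% of changes of 1 on the log2 scale and 93.3% of changes of 2, with 7.7 false calls per dataset on average. A list of 30 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 10 of 10 datasets and an unshifted list in 0. The simulated genes varied independently of each other. In the data the estimated correlation was 0.16 for the progenitor and 0.53 for the ribosomal list. The simulation therefore cannot show how often camera at its preset correlation calls such lists falsely. With 2 samples per group an exact permutation test cannot give a p below 0.333. The labels do not say that the samples came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The alternatives tried were other pseudocounts, filters, scalings, limma settings and list tests, a replicate block, leaving out each library and, added after the data were seen, the myeloid marker level as a covariate and protein-coding genes only. Genome positions are those of the deposited table on mm10; exons of Acss2 and its antisense gene were taken from the GENCODE annotation of the same build.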

Results

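CD8+ T cells that had infiltrated B16-GP33 tumours in mice were profiled by RNA sequencing at day 21. B16 is a mouse melanoma line, and GP33 is an epitope of lymphocytic choriomeningitis virus that CD8+ T cells recognise. The data comprised 2 libraries of T cells labelled EV, the control, and 2 labelled ACSS2NLS. ACSS2 makes acetyl-CoA from acetate, and NLS is the usual abbreviation of a nuclear localisation signal. Each library held 46000000 to 49300000 tags, to the nearest 100000, of which 39.6% to 41.9% lay on exons in the sense direction, and 9810 genes had a mean of at least 1 FPKM. The comparison of ACSS2NLS with EV addressed which exhausted T cell state changed in its gene expression in cells labelled ACSS2NLS. No group had added ACSS2 without the signal, so a higher level of ACSS2 and its location cannot be told apart. Where the protein lay was not measured in these data.

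Acss2 itself was far higher in the ACSS2NLS cells. Its level was 3.66 and 3.92 FPKM in the EV libraries and 80.7 and 86.3 FPKM in the ACSS2NLS libraries, so the labels matched the level of the gene. Acss2 (NM_019811; mm10 chromosome 2, 155518043 to 155562743, plus strand) rose 22.0-fold in mean FPKM, and by 4.14 ± 0.11 (SE, n = 2 per group) on the log2(FPKM + 1) scale (limma-trend, adjusted p = 0.000931). The antisense gene Acss2os (NR_040613; chromosome 2, 155547040 to 155556930, minus strand), a noncoding RNA that shares 113 exon bases with Acss2, rose from 1.08 and 0.974 FPKM to 28.8 and 32.2 FPKM (log2 change 3.96 ± 0.13, adjusted p = 0.00152). Its reads cannot be separated with certainty from those of Acss2. Among the other enzymes that supply acetyl-CoA, Acly, which makes it from citrate, was at 46.6 ± 0.827 FPKM in EV and 43.7 ± 6.66 FPKM in ACSS2NLS (SD, n = 2; log2 change -0.10 ± 0.14). Acss1, the mitochondrial counterpart of ACSS2, was at 11.1 ± 0.119 and 9.60 ± 0.524 FPKM (log2 change -0.19 ± 0.12). Neither passed the test.

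Of the 9810 genes, these 2 passed the limma-trend threshold upward and 0 passed downward, while 304 genes were higher and 282 lower at an unadjusted p under 0.05, against 490.5 expected by chance in both directions. The groups did not overlap for 37.4% of genes, where chance gives 33.3%. Without EV replicate 1 some genes passed downward, S100a8 and S100a9 among them. That fit has a lone EV library, so its residual spread comes from the ACSS2NLS libraries alone. In the EV library kept, S100a8 was at 24.4 FPKM, against 3.21 FPKM in EV replicate 1. With the myeloid marker level as a covariate, 188 genes passed upward, Id3, Slamf6, Tcf7 and Egr2 among them, and 180 downward, with Il7r, Gzmb and Dusp2. That fit has a single residual degree of freedom and takes its spread from the trend over all genes. In the limma fit of the 2 groups with all 4 libraries and no further term, no other single gene passed over all genes tested. Of the changes described from here on, some passed for a gene list or within a list, and others passed neither way.

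**Figure D1:**
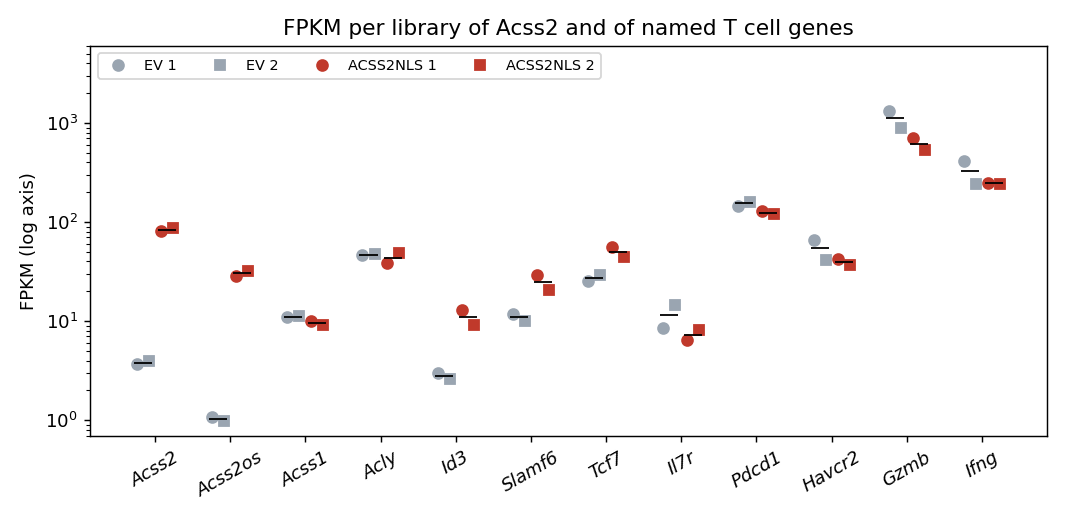
FPKM of named genes in each library on a log axis, with EV in grey and ACSS2NLS in red, replicate 1 as circles, replicate 2 as squares, and group means as black lines. Acss2 and Acss2os lie far above both EV libraries in both ACSS2NLS libraries, while Acly and Ifng overlap between the groups.

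Genes of progenitor exhausted and memory T cells were higher as a group in ACSS2NLS. Of the 27 measured, 20 had a higher and 7 a lower mean, with a median log2 change of 0.24, and the list was higher than other genes (camera, adjusted p = 0.00839; adjusted p = 0.689 with an estimated correlation). Adjusted over the list alone, 4 genes rose and 0 fell, while 0 passed over all genes tested. These were Id3, a transcriptional regulator of memory precursors, Slamf6, a surface marker of progenitor exhausted cells, Tcf7, which encodes TCF1, the transcription factor that maintains them, and S1pr1, a receptor for tissue egress. Id3 was at 2.98 and 2.63 FPKM in EV and 13.0 and 9.08 FPKM in ACSS2NLS (log2 change 1.64 ± 0.20, adjusted p = 0.0071 over the list alone). Slamf6 was 2.29-fold and Tcf7 1.81-fold higher (log2 changes 1.10 ± 0.20 and 0.83 ± 0.15, adjusted p = 0.0206 for each over the list alone), and S1pr1 was 2.15-fold higher (0.75 ± 0.18, adjusted p = 0.0427 over the list alone).

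Other members of that list did not pass. Il7r, the IL-7 receptor chain of memory cells, had a log2 change of -0.57 ± 0.26, with both ACSS2NLS libraries below both EV libraries. The mean level of the list relative to its mean over the libraries was -0.18 and -0.051 in EV replicates 1 and 2 and 0.22 and 0.017 in ACSS2NLS replicates 1 and 2. Without ACSS2NLS replicate 1 the list no longer passed (adjusted p = 0.375) and its median log2 change was 0.12; among genes with a mean of at least 5 FPKM it passed (adjusted p = 0.0159) with a median of 0.11.

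Genes of terminal exhaustion were on balance lower in ACSS2NLS, but not past the threshold. Of the 30 measured, 17 had a lower and 13 a higher mean, with a median log2 change of -0.10 (camera, adjusted p = 0.0944; adjusted p = 0.689 with an estimated correlation). Adjusted over the list alone, Id2, a regulator of effector differentiation, fell by 0.80 on the log2 scale and the protease inhibitor Serpina3g fell by 0.64 (adjusted p = 0.0478 for each), while the surface protein Cd7 rose by 0.79 (adjusted p = 0.0252); over all genes tested 0 passed. The inhibitory receptor Pdcd1 was at 154 ± 10.2 FPKM in EV and 125 ± 6.64 FPKM in ACSS2NLS (log2 change -0.30 ± 0.13). Havcr2, which encodes TIM-3, had a log2 change of -0.41 ± 0.23, and Tox, the transcription factor of exhausted cells, had 0.29 ± 0.18. None of Pdcd1, Havcr2 and Tox passed. Without EV replicate 1 the direction of the camera test turned upward (adjusted p = 0.926), and without EV replicate 2 or ACSS2NLS replicate 1 it passed downward (adjusted p = 0.00109 and 0.019).

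**Figure D2:**
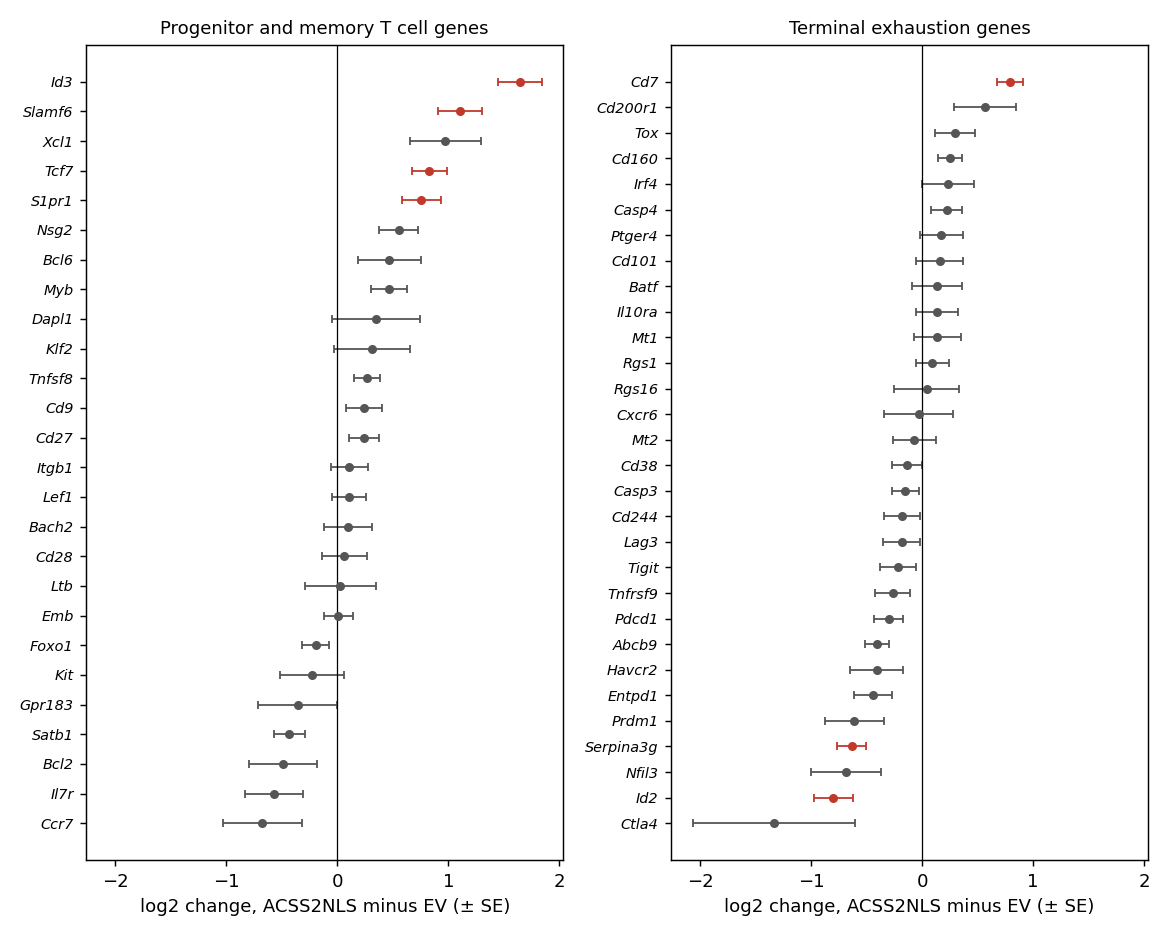
Log2 change of ACSS2NLS against EV, with standard errors from limma, of the progenitor and memory genes (left, 26 genes drawn) and the terminal exhaustion genes (right, 30 genes drawn). Red points passed adjusted over their list alone: Id3, Slamf6, Tcf7 and S1pr1 on the left, and Cd7 above and Serpina3g and Id2 below 0 on the right.

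Cytotoxic effector genes did not differ past the threshold in the fit of the 2 groups alone. Their list had 15 of 22 genes lower and a median log2 change of -0.084 (camera, adjusted p = 0.139, and 0.689 with an estimated correlation). It passed downward with the replicate block and with the myeloid covariate (camera, adjusted p = 0.0262 and 0.0165). Its median was -0.027 and -0.14 without EV replicates 1 and 2, and -0.040 and -0.12 without ACSS2NLS replicates 1 and 2. Gzmb, which encodes granzyme B, was at 1334 and 890 FPKM in EV and 706 and 528 FPKM in ACSS2NLS (log2 change -0.83 ± 0.29), and the NK receptor gene Klrb1c had a log2 change of -0.57 ± 0.22. Ifng, which encodes interferon gamma, was at 413 and 243 FPKM in EV and 247 and 245 FPKM in ACSS2NLS (-0.37 ± 0.27), and turned to 0.014 without EV replicate 1. The cytokine and chemokine list was higher, with 12 of 14 genes up in mean and a median log2 change of 0.22 (camera, adjusted p = 0.0472; adjusted p = 0.689 with an estimated correlation). Lta, which encodes lymphotoxin alpha, was 1.53-fold higher (log2 change 0.56 ± 0.12), and 0 genes passed over this list alone. Without ACSS2NLS replicate 2, the library with the highest level of melanoma markers, the cytokine list had an adjusted p of 0.993 and a median of -0.12; without ACSS2NLS replicate 1 it had an adjusted p of 0.000654 and a median of 0.57. With a pseudocount of 0.1 or 0.5, no filter on low values or a mean of at least 5 FPKM it missed the threshold too (adjusted p = 0.0676, 0.0562, 0.32 and 0.0563), with medians of 0.28, 0.25, 0.19 and 0.33.

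Immediate early and TCR response genes were lower as a group, with 17 of 22 lower in mean and a median log2 change of -0.53 (camera, adjusted p = 0.00431; adjusted p = 0.689 with an estimated correlation). Dusp2, a phosphatase that restrains MAP kinases, was at 284 ± 74.7 FPKM in EV and 129 ± 29.3 FPKM in ACSS2NLS (log2 change -1.13 ± 0.25). Egr2, a transcription factor induced by TCR signals, was higher, at 12.7 ± 2.63 and 29.3 ± 11.1 FPKM (1.10 ± 0.28); neither passed. The list no longer passed without EV replicate 1 (adjusted p = 0.15, median -0.16) or ACSS2NLS replicate 2 (adjusted p = 0.614, median -0.23), the libraries with the lowest and the highest melanoma marker levels. Without EV replicate 2 or ACSS2NLS replicate 1 the median was -0.83 and -0.79.

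Among the 8 lists that passed, the 2 that kept their call whichever library was left out were the ribosomal and the proliferation genes. Of 45 cytosolic ribosomal protein genes, 44 had a higher mean in ACSS2NLS and 36 were higher in both ACSS2NLS libraries than in both EV libraries, with a median log2 change of 0.28 (camera, adjusted p = 2.5e-12; adjusted p = 0.689 with an estimated correlation). Rps23 and Rpl14 had log2 changes of 0.54 ± 0.14 and 0.44 ± 0.14. Of 40 proliferation genes, 34 had a lower mean and 22 were lower in both ACSS2NLS libraries than in both EV libraries, with a median log2 change of -0.16 (camera, adjusted p = 7.69e-06; adjusted p = 0.689 with an estimated correlation). The mitotic cyclin Ccnb2 and the cell cycle transcription factor Mybl2 had log2 changes of -0.35 ± 0.11 and -0.34 ± 0.13. No gene of either list passed over all genes or over its list alone. Without ACSS2NLS replicate 1 the median of the ribosomal list was 0.15 and that of the proliferation list -0.095.

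Heat shock genes were higher, with 12 of 14 up in mean and a median log2 change of 0.27 (camera, adjusted p = 0.00431; adjusted p = 0.689 with an estimated correlation). The mitochondrial chaperonin Hspe1 and the cytosolic chaperone Hsp90aa1 had log2 changes of 0.73 ± 0.16 and 0.65 ± 0.17. This call was lost without ACSS2NLS replicate 1 (adjusted p = 0.556, median 0.20), where the inducible Hspa1a stood at 24.1 FPKM against 1.54 to 3.60 FPKM in the other libraries, or without EV replicate 2 (adjusted p = 0.249, median 0.22). Without EV replicate 1 or ACSS2NLS replicate 2 the median was 0.44 and 0.45. Cholesterol synthesis genes were slightly higher, with 17 of 22 up in mean and a median of 0.12 (camera, adjusted p = 0.0243; adjusted p = 0.689 with an estimated correlation). Hmgcs1 and Msmo1 had log2 changes of 0.37 ± 0.18 and 0.30 ± 0.14, and neither passed. The call of the list was lost without EV replicate 1 (adjusted p = 0.15, median 0.079) or ACSS2NLS replicate 2 (adjusted p = 0.334, median 0.041), the libraries with the lowest and the highest melanoma marker levels. Without EV replicate 2 or ACSS2NLS replicate 1 the median was 0.19 and 0.20, and with a mean of at least 5 FPKM it was 0.20. Under quantile normalization (adjusted p = 0.0523) and with the myeloid marker level as a covariate (adjusted p = 0.0745) the list missed the threshold with medians of 0.12 and 0.11, about as large as before.

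The acetyl-CoA and lipogenesis, histone acetylation, oxidative phosphorylation, glycolysis, interferon stimulated and tissue residency lists did not pass with all libraries. The acetyl-CoA and lipogenesis list had 8 genes higher and 10 lower (camera, adjusted p = 0.678), and its median of -0.013 and mean of 0.034 differed in sign. The desaturase gene Scd2 had a log2 change of 0.65 ± 0.21. The histone acetylation list, of acetyltransferases, deacetylases and acetyl-lysine readers, had 16 higher and 12 lower (median 0.022, adjusted p = 0.965), with Hdac5 at -0.23 ± 0.14 and Tada3 at 0.21 ± 0.13. Oxidative phosphorylation genes had 33 of 42 higher (median 0.070, adjusted p = 0.0712), glycolysis genes 10 of 18 lower (median -0.050, adjusted p = 0.139), interferon stimulated genes 15 of 26 lower (median -0.021, adjusted p = 0.139) and tissue residency genes 6 of 7 higher (median 0.12, adjusted p = 0.352). Single libraries decided several of these results. Without ACSS2NLS replicate 1 the camera direction of the oxidative phosphorylation, glycolysis, tissue residency and acetyl-CoA lists turned (adjusted p = 0.218, 0.986, 0.986 and 0.567). Oxidative phosphorylation genes passed upward without EV replicate 1 or ACSS2NLS replicate 2 (adjusted p = 0.0111 and 2.57e-06), under quantile normalization (adjusted p = 0.000422), with a mean of at least 5 FPKM (adjusted p = 0.0263) and with the myeloid covariate (adjusted p = 0.0223). Glycolysis genes passed downward without EV replicate 2 or ACSS2NLS replicate 2 (adjusted p = 0.0185 and 0.0237), and interferon stimulated genes without EV replicate 1 (adjusted p = 0.00752). With an estimated correlation and all libraries these lists had adjusted p = 0.725 (oxidative phosphorylation), adjusted p = 0.725 (glycolysis) and adjusted p = 0.689 (interferon).

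Outside the lists, the genes with the smallest unadjusted p did not pass over all genes tested. Trim59 had a log2 change of 0.80 ± 0.12 (adjusted p = 0.742). Lower in ACSS2NLS were Serpina3f (-1.11 ± 0.12), the adhesion receptor gene Adgrg5 (-1.02 ± 0.12; adjusted p = 0.43 for each), Styk1 (-1.21 ± 0.14, adjusted p = 0.43), the cold-inducible RNA-binding protein gene Cirbp (-0.95 ± 0.13) and the MYC antagonist gene Mxd1 (-0.96 ± 0.13; adjusted p = 0.616 for each).

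Transcripts of other cells of the tumour were present and varied between libraries. The mean level of 9 melanoma markers, relative to its mean over the libraries, was -1.26 and 0.20 in EV replicates 1 and 2 and -0.80 and 1.86 in ACSS2NLS replicates 1 and 2. All 9 had a higher mean in ACSS2NLS (median log2 change 1.19; camera, adjusted p = 0.0243; adjusted p = 0.689 with an estimated correlation), but the list missed the threshold without EV replicate 1 (adjusted p = 0.288, median 0.32) and with no filter on low values (adjusted p = 0.076, median 0.59). Without EV replicate 2 or ACSS2NLS replicate 1 its median was 1.98 and 2.78. Without ACSS2NLS replicate 2 its direction turned (adjusted p = 0.614, median -0.33), and the pigment cell gene Mlana went from a log2 change of 1.19 ± 0.85 to -0.12. The myeloid markers were at -1.22 and 0.86 in EV and -0.58 and 0.93 in ACSS2NLS, with 20 of 25 higher in mean (adjusted p = 0.151). That list passed upward without EV replicate 2 or ACSS2NLS replicate 1 (adjusted p = 3.95e-09 and 0.00142), passed downward without EV replicate 1 (adjusted p = 1.72e-05) and turned downward without ACSS2NLS replicate 2 (adjusted p = 0.466); with an estimated correlation and all libraries it had adjusted p = 0.845. Within it, the neutrophil genes S100a8 and S100a9 were lower in ACSS2NLS. S100a8 was at 3.21 and 24.4 FPKM in EV and 0.053 and 0.802 FPKM in ACSS2NLS (log2 change -2.91 ± 0.83, limma adjusted p = 0.81). Without EV replicate 1, which leaves a lone EV library, its log2 change was -4.20. The CD4 and regulatory T cell list had 5 genes higher and 5 lower (adjusted p = 0.385); Tnfrsf18 and Tnfrsf4, which activated CD8+ cells also express, had log2 changes of -0.56 ± 0.15 and -0.57 ± 0.15. The list of stromal, endothelial and red blood cell markers had 5 of 7 higher (adjusted p = 0.135), with Col1a1 at 0.529 ± 0.658 and 1.91 ± 0.673 FPKM; the list passed upward without EV replicate 2 or ACSS2NLS replicate 2 (adjusted p = 0.00105 and 0.00282) and turned without ACSS2NLS replicate 1 (adjusted p = 0.671), and with an estimated correlation and all libraries it had adjusted p = 0.689. The B cell markers Jchain and Cd79b had log2 changes of 1.15 ± 0.41 and 0.39 ± 0.19. With no filter on low values, 9 B cell markers were higher as a group (median 0.11; camera at the preset correlation, adjusted p = 0.0162) and 12 NK and gamma-delta T cell markers did not pass (adjusted p = 0.899). Of the 2 measured NK and gamma-delta T cell markers, Gzmm had a log2 change of 0.23 ± 0.21. Eomes, a T-box transcription factor that memory and exhausted CD8+ cells also express, was 1.90-fold higher, with 4.23 and 5.52 FPKM in EV and 9.34 and 9.16 FPKM in ACSS2NLS (log2 change 0.81 ± 0.16; limma adjusted p = 0.00555 over the list alone, 0.775 over all genes).

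**Figure D3:**
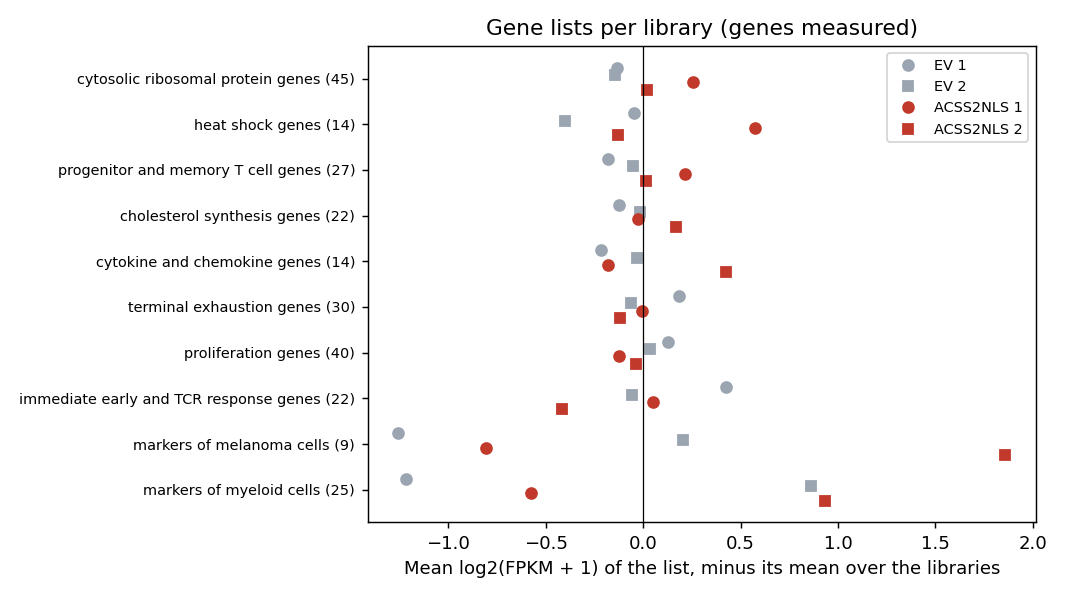
Mean log2(FPKM + 1) of each gene list in each library, minus its mean over the 4 libraries, with the number of measured genes in brackets (EV in grey, ACSS2NLS in red; replicate 1 as circles, replicate 2 as squares). Ribosomal genes are higher and proliferation genes lower in both ACSS2NLS libraries than in both EV libraries, while the melanoma and myeloid markers differ more between replicates than between groups.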

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

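The myeloid covariate and the protein-coding set were chosen after the data were seen. The Acss2 level passed under every alternative run, with a log2 change of 4.09 to 4.43. Acss2os passed in all but 2: with no filter on low values 1 gene passed upward, and among protein-coding genes 1 did, since Acss2os is noncoding. Camera called 7 to 12 lists with its preset correlation, but 0 with an estimated correlation and 0 with fry. For the progenitor list the adjusted p was then 0.689 and 0.666. With 2 residual degrees of freedom these 2 tests had little power. The ribosomal list, with 44 of 45 genes higher, had an unadjusted p of 0.213 (camera, estimated correlation) and 0.126 (fry). Many lists share the value 0.689 through the Benjamini-Hochberg adjustment, so it is not separate evidence on each. The sum over rows of a symbol was not run, since no symbol had more than 1 row, and the lists were not retested with robust or untrended limma, which leave the matrix as it was.

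With the replicate block 229 genes passed upward and 172 downward, and with the myeloid marker level as a covariate 188 and 180. Both fits called 302 genes, among them Id3, Slamf6, Tcf7 and Egr2 upward and Il7r, Gzmb and Dusp2 downward. Of the progenitor list, 5 genes passed upward and 1 downward with the block, and 8 and 4 with the covariate. Each fit has a single residual degree of freedom. The myeloid level was -1.22 and 0.86 in EV replicates 1 and 2 and -0.58 and 0.93 in ACSS2NLS replicates 1 and 2. Within the groups it thus follows the replicate number, so the shared calls are not separate support. The replicate numbers are not stated to pair the samples. Their deviations from the group means correlated over genes (r = 0.58), and 17 myeloid and 7 melanoma markers were among the calls of the block. Under the block the terminal exhaustion list passed (adjusted p = 0.0285), as did the cytotoxic effector list downward (0.0262) and the myeloid and stromal lists upward (9.48e-10 and 0.0262). With the covariate the cytotoxic effector list (0.0165), the interferon list (0.0481), the stromal list (0.00752) and the myeloid list (0.02) passed as well. The covariate is the mean of the myeloid list itself, so that list's call there is no evidence of a remaining difference. With all libraries kept, lists with no call changed direction in 4 cases: acetyl-CoA and lipogenesis under quantile normalization (adjusted p = 0.968), and histone acetylation with no filter (0.975), the block (0.96) and the covariate (0.999). The causes were not tested.

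A lone library in a group was assumed to vary like the other group. With each library left out in turn, 0 to 9 genes passed downward, the 9 without EV replicate 1: Cd14, Cxcl2, Cxcl3, Il1b, Lcn2, Mir7678, S100a8, S100a9 and Slpi. The list adjusted p ranged from 6.17e-05 to 0.375 for progenitor, 0.00109 to 0.926 for terminal exhaustion, 0.203 to 0.986 for tissue residency, 0.303 to 0.926 for acetyl-CoA and lipogenesis, 0.0185 to 0.986 for glycolysis, 2.57e-06 to 0.712 for oxidative phosphorylation, 0.718 to 0.956 for histone acetylation (turned downward without EV replicate 2, 0.788, or ACSS2NLS replicate 2, 0.922), 7.36e-08 to 0.614 for melanoma, 3.95e-09 to 0.466 for myeloid and 0.00105 to 0.671 for stromal genes. The log2 change ranged from -0.75 to 0.014 for Ifng, -0.25 to 0.053 for Acly and -0.12 to 2.501 for Mlana. In the simulation, with 2 libraries per group, 36.4% of log2 changes of 1 were recovered. It planted 200 changed genes that varied independently, so it does not give the share of changes missed in these data.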

Other observations

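The test of Acss2os was set before its result was seen; the other tests here were chosen after. Gzmc to Gzmf and Ccl1 were chosen for description after their values were seen.

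The granzyme genes Gzmc, Gzmd, Gzme and Gzmf were higher in replicate 2 than in replicate 1 of both groups: Gzmc was at 30.7 and 87.1 FPKM in EV and 15.5 and 89.0 FPKM in ACSS2NLS, and Gzmf at 16.5 and 33.9 FPKM in EV and 3.14 and 27.1 FPKM in ACSS2NLS. The chemokine gene Ccl1 did the same, with 45.0 and 120 FPKM in EV and 66.1 and 153 FPKM in ACSS2NLS. The difference between the progenitor and the terminal exhaustion list means, relative to its mean over the libraries, was -0.36 and 0.0091 in EV replicates 1 and 2, and 0.22 and 0.13 in ACSS2NLS replicates 1 and 2.

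Acss2os rose with Acss2, and reads of the Acss2 construct counted on the overlapping antisense gene are a candidate explanation. The 113 shared exon bases make up 18.0% of Acss2os and lie within the coding sequence of Acss2. If reads covered Acss2 evenly and without regard to strand, they would give 0.486 ± 0.015 (SD, 2 libraries) of the observed rise in FPKM. The bound set in advance was 0.5, and a value under it counted against the explanation. The value fell under that bound, but by less than the SD, a margin that the bound did not include. Since the value also rests on even coverage, the test is not taken to decide. Reads of a construct with coding sequence only would be denser over the shared bases than assumed here, which keeps the explanation open, as does transcription of Acss2os itself.

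The progenitor and memory genes were higher in ACSS2NLS. With the myeloid marker level as a covariate the list still passed (camera, adjusted p = 0.000533). The melanoma markers passed too (camera, adjusted p = 9.33e-08), so the covariate did not remove all signal of other cells. Their RNA stays open as a cause. The myeloid markers also passed (camera, adjusted p = 0.02), but the covariate is their own mean. Their mean change is thus fixed by construction in that fit, and their call is no evidence of what remains. In that fit 8 genes of the progenitor list passed upward and 4 downward (Il7r, Ccr7, Satb1 and Bcl2, with log2 changes of -0.67, -0.68, -0.47 and -0.58). The list also passed under quantile normalization (adjusted p = 0.00261, median log2 change 0.25), which argues against a scaling that depends on expression level. Both calls use the preset correlation; with no covariate or rescaling the list did not pass with an estimated correlation (adjusted p = 0.689). ACSS2NLS replicate 1 had the highest mean level of the progenitor, heat shock and ribosomal lists (0.22, 0.57 and 0.26, relative to each list's mean over the libraries). Whether that library carries the change of the progenitor list cannot be told apart from a shared change. Without it the median log2 change of that list was 0.116, against 0.120 for 0.5 of the value with all libraries. By the rule used, a value under 0.120 goes with that library carrying the change, and 0.116 is just under it. The bootstrap SD over genes was 0.109, far more than that difference. That SD treats the genes as independent and does not measure the spread between libraries. An effect of the construct stays open too; over all alternatives the adjusted p ran from 6.17e-05 to 0.689.

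Melanoma and myeloid markers differed between libraries of a group. Replicates differed by 1.46 (EV) and 2.66 (ACSS2NLS) on the log2 scale in the melanoma list, where the groups differed by 1.05, and by 2.08 and 1.51 in the myeloid list, where the groups differed by 0.35. Among abundant markers, Lyz2 ranged from 18.0 to 233 FPKM and Apoe from 7.19 to 187 FPKM. Between ACSS2NLS replicate 2 and EV replicate 2, the neutrophil genes S100a8, S100a9 and Csf3r differed by -4.16 to -0.51 and the macrophage genes C1qa, C1qb, C1qc, Apoe and Adgre1 by 0.68 to 1.302 on the log2 scale, in 1 library against 1 and in genes picked after their values were seen. No explanation of these differences was tested, and how many of the listed markers CD8+ T cells express themselves was not measured. The labels describe the cells as CD8+, and whether a sort removed other cells is not given in the sources used here.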
